A study of Drosophila melanogaster with 6 samples.

How the data were processed

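RNA was measured in adult Drosophila heads of flies whose Zn72D gene carries a GFP protein trap, in 3 anti-GFP immunoprecipitates (RIP) and 3 inputs. Per the labels' protocols, flies were kept at 25 C with 12 hours of light and 12 of dark, males and females were pooled, and the lysate was precipitated and washed 8 times. The extract protocol gives the input as 4% of the lysate and the design text gives 5%. Both groups went through an rRNA removal step with antisense DNA oligonucleotides covering rRNA in sections of 50 bases and a heat-stable RNase H, and libraries were made with a KAPA RNA kit, per the labels' protocols.

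The submitters' processing notes name Trim Galore 0.4.5, STAR 2.5.4b, RSEM 1.2.30, DESeq2 1.20.0 and the genome build dm6. The annotation release and the strand setting are not given in the sources used here. Per the file headers, the authors' deposited values are RSEM expected counts, TPM, transcript length and effective length for each of 17453 genes in each library. Expected counts divide reads that match several genes between them, and about 95% of them, zeros included, were exactly whole as listed (no tolerance). TPM, as the authors deposited it, is divided by effective length and by the sum over all genes, rRNA included, so a library with more rRNA has lower TPM for every other gene. Effective length, per the file headers, was used for a mean fragment length, which was 172, 171 and 162 bases in input and 195, 195 and 207 in RIP.

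Gene symbols, biotypes and dm6 coordinates came from an Ensembl annotation: 17179 IDs matched directly, 199 through their transcript IDs and 75 had no symbol. Expected counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr (11670 genes), scaled by TMM and tested with edgeR's quasi-likelihood test with the group as the only term and Benjamini-Hochberg adjustment at 0.05 (R 4.3.3, edgeR 4.0.16, limma 3.58.1). Standard errors were derived from the fold change and its F statistic. TMM factors were 0.479, 0.608 and 0.507 in input and 1.99, 2.01 and 1.70 in RIP. TMM assumes that most genes do not differ between the groups, which a precipitation need not meet, so fold changes are relative to the bulk of genes.

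Gene lists, 23 in number, were fixed before the data were examined, and 22 had at least 3 measured members and were tested with camera (preset correlation 0.01), again with an estimated correlation, and with fry. The genes named in the text follow a rule also fixed then: 8 fixed genes; the 10 highest and 10 lowest fold changes among genes past the threshold whose groups did not overlap, with a mean CPM of 5 or more and a mean length of 200 or more, outside rRNA; and for each list the 2 members with the smallest p in the main direction and 1 in the other. X-linked and autosomal genes were compared with Fisher's exact test, and transcript features with Spearman's rho across genes. GC content, also planned, was not tested because no genome sequence was used here.

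Genes with at least 1 count numbered 13328 to 13764 in input and 14064 to 15093 in RIP. Counts of replicates differed by more than sampling noise in every pair (chi-square per degree of freedom 14.8 to 138), so none was taken as a repeat run of another library. All 6 were kept as separate samples, though this check does not tell separate fly collections from separate library preparations. The test was checked on simulated counts of 11346 genes for RIP against input: it recovered 7.46% of 67 genes changed 1.5-fold, 43.3% of 67 changed 2-fold and 92.4% of 66 changed 4-fold, and 4 of its 99 calls were false. Few genes were changed there, all well counted and equally often up and down, and no rRNA shift was included. The real comparison called 4351 genes, so these shares need not hold for it. In the same simulation a planted list was called and 0 of 20 unchanged lists were. Genes were drawn independently there, so this does not check camera on lists whose genes move together. Other splits of the real libraries called 9 to 16 lists with no gene called. Input and RIP libraries are unequally shared between the sides of those splits, so part of the RIP-input difference stays in them.

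The labels number replicates 1 to 3 in both groups without saying what a number marks. Deviations from the group means correlated across genes at 0.665, 0.604 and 0.848 between same-numbered input and RIP libraries. Libraries numbered 1 and 2 correlated about as well across numbers (0.626 for input 1 with RIP 2 and 0.604 for input 2 with RIP 1), while replicate 3 correlated at -0.789 to -0.659 with the other numbers, so the check sets replicate 3 apart and does not tell 1 from 2. Every same-numbered pair being above 0.1, the numbers were taken to pair the samples, and a fit with the replicate number as a block was run beside the main one. The common dispersion was 0.102 without and 0.0079 with the block.

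Alternatives fixed before the data were examined were other scalings (RLE, upper quartile, library size only), leaving out rRNA and genes under 200 bases, no filter and a stricter filter (1 CPM in 3 libraries and a mean count of 50), DESeq2 1.42.0, limma-voom, limma-trend on log2(TPM + 1), an adjusted p of 0.01, the replicate block, removal of the length trend by loess (span 0.3) alone and with the block, and leaving out each library. Leaving out rRNA genes alone, thinning all libraries to 5864713 non-rRNA counts and leaving out both replicate 3 libraries were added after seeing the data. Medians of lists were also set against 10000 random lists matched on length and mean expression, each member drawn from its 50 nearest genes. Members were drawn independently, so the ranges do not allow for genes that move together. Tables and figures were prepared with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.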

Results

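RNA recovered with the Drosophila protein Zn72D was measured in adult fly heads. Zn72D is a zinc finger RNA-binding protein with known roles in dosage compensation of the X chromosome and in RNA editing by Adar. The flies, males and females pooled, carried a protein trap that fuses GFP to Zn72D, and RNA was recovered from head lysate after immunoprecipitation with an antibody against GFP (RIP). A small part of the lysate served as input. The libraries were 3 RIP and 3 input libraries, numbered 1 to 3 in each group, made after an rRNA removal step with antisense oligonucleotides and RNase H, per the labels. No mock or untagged precipitation was analysed here, so every enrichment is relative to input. Nothing in the sources used here says that the 3 numbers came from separate collections of flies, so p-values measure the spread between these samples, which may be technical. Part of that spread is a difference of replicate 3 that input and RIP share (correlation 0.848), which the main fit leaves in.

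The input libraries held 34401553, 35772972 and 38331703 expected counts and the RIP libraries 38182015, 37406162 and 28070655. rRNA made up 79.9% ± 2.67 (SD, n = 3) of the input counts and 6.55% ± 2.49 of the RIP counts, so most input counts were rRNA although the labels give the same removal step for both groups. Outside rRNA, 5864723, 7852065 and 8182107 counts were left in the input libraries and 36377598, 35332929 and 25434735 in the RIP libraries. Protein-coding genes took 17.9% ± 2.48 of the input and 91.5% ± 2.37 of the RIP counts. The 7SL RNA genes, which encode the RNA of the signal recognition particle, took 1.57% ± 0.125 of the input and 0.0507% ± 0.0161 of the RIP counts. No mitochondrially encoded gene is listed in the tables used here, so that list was not tested.

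**Figure D1:**
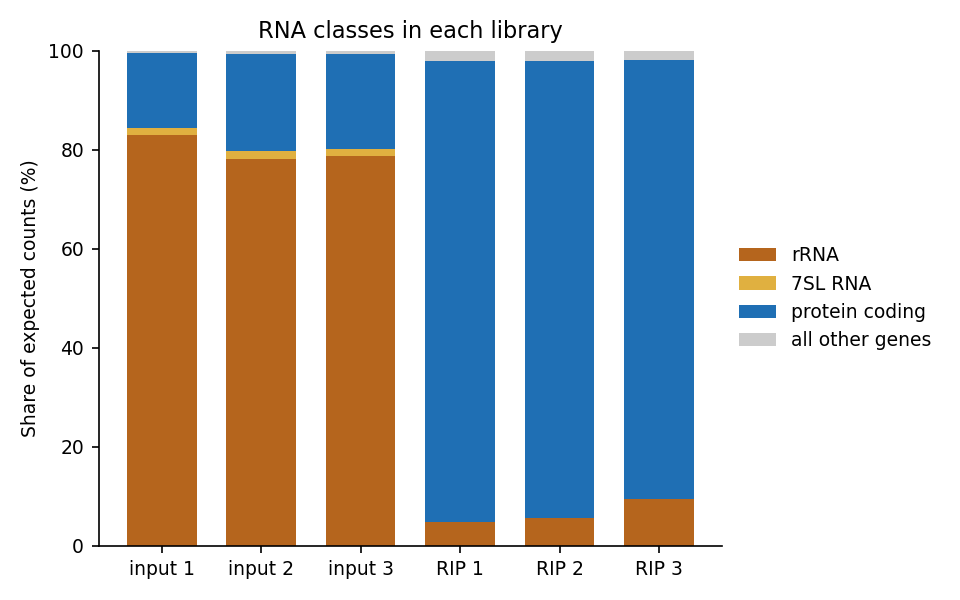
Share of expected counts (%) taken by rRNA, 7SL RNA, protein-coding genes and all other genes in each of the 3 input and 3 RIP libraries, as stacked bars. rRNA averages 79.9% in input and 6.55% in RIP, and protein-coding genes 17.9% and 91.5%.

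The RIP and input libraries were compared to find which RNAs are recovered with Zn72D. Among the 8 genes named in advance, the RNAs of Adar, the enzyme that edits adenosine in RNA, and of roX1, a noncoding RNA of the dosage compensation complex, were about 3 times as abundant in RIP as in input. Adar (FBgn0026086; dm6 chromosome X, 1773725 to 1788065) had 99.7 ± 20.99 CPM in input and 301 ± 97.8 CPM in RIP (SD, n = 3). Its log2 fold change was 1.59 ± 0.27 (SE; edgeR adjusted p = 0.00501). The CPM of roX1 (FBgn0019661; X, 3857230 to 3862697) rose from 468 ± 14.9 to 1485 ± 209, a log2 fold change of 1.66 ± 0.14 (edgeR adjusted p = 0.000513). The other noncoding RNA of that complex, roX2, had 17.6 ± 4.93 CPM in input and 14.4 ± 6.77 in RIP, and its log2 fold change of -0.29 ± 0.38 did not pass the test (edgeR adjusted p = 0.606).

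Of the protein-coding genes of dosage compensation, msl-2, which is translated in males only, rose 2.38-fold (log2 1.25 ± 0.08, edgeR adjusted p = 0.000322) and mle, the helicase whose splicing depends on Zn72D, rose 1.74-fold (log2 0.80 ± 0.09, edgeR adjusted p = 0.00128). The RNA of Zn72D itself rose 1.40-fold, from 50.5 ± 2.78 to 70.5 ± 3.41 CPM (log2 0.48 ± 0.08, edgeR adjusted p = 0.00558). The ribosomal protein gene RpL32 was 9.88-fold lower in RIP (log2 -3.30 ± 0.14, edgeR adjusted p = 0.000135). The cytoplasmic actin gene Act5C had 383 ± 23.4 CPM in input and 331 ± 44.5 in RIP (log2 -0.21 ± 0.12, edgeR adjusted p = 0.246). For Zn72D, Adar, roX1, mle and msl-2 the 3 RIP values all lay above the 3 input values, and for RpL32 all below.

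The call for Zn72D ended when RIP replicate 2 was left out (adjusted p = 0.0622) and when the length trend was removed (log2 -0.01, adjusted p = 0.97), within a range of 1.83e-06 to 0.97 over 22 alternatives. With the replicate number as a block, roX2 (log2 -0.34, adjusted p = 0.013) and Act5C (log2 -0.22, adjusted p = 0.0339) were called lower, within ranges over the alternatives of 0.000136 to 0.951 and 2.16e-06 to 0.543, and both had positive values under library-size scaling and in TPM, where the medians of all genes were 1.90 and 2.54 (below 0 otherwise, except roX2 without its length trend). With the block and the length trend removed, roX2 was instead called higher (log2 0.67, adjusted p = 0.00683), so its direction under the blocked fits depends on the length trend. Both were also called lower without both replicate 3 libraries (log2 -0.71, adjusted p = 0.00752 for roX2, and -0.44, adjusted p = 0.00053 for Act5C), and Act5C without RIP replicate 3 alone (-0.44, adjusted p = 0.00616) and with upper quartile scaling (-0.32, adjusted p = 0.0414). Removing the length trend left the calls of mle, msl-2, RpL32, Adar and roX1 with smaller folds. Here mle stood at log2 0.25 (adjusted p = 0.0355, within 2.24e-08 to 0.0355), msl-2 at 0.74, the ribosomal protein gene RpL32 at -1.85 and Adar at 0.94 (adjusted p = 0.0387, within 1.58e-12 to 0.0387). Over all alternatives roX1 stood at 1.155 or more (adjusted p up to 0.00754). Exons of Adar overlap those of prage on the same strand, and exons of roX1 overlap those of ec on the other strand; the sources used here do not state whether counting used strand.

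**Figure D2:**
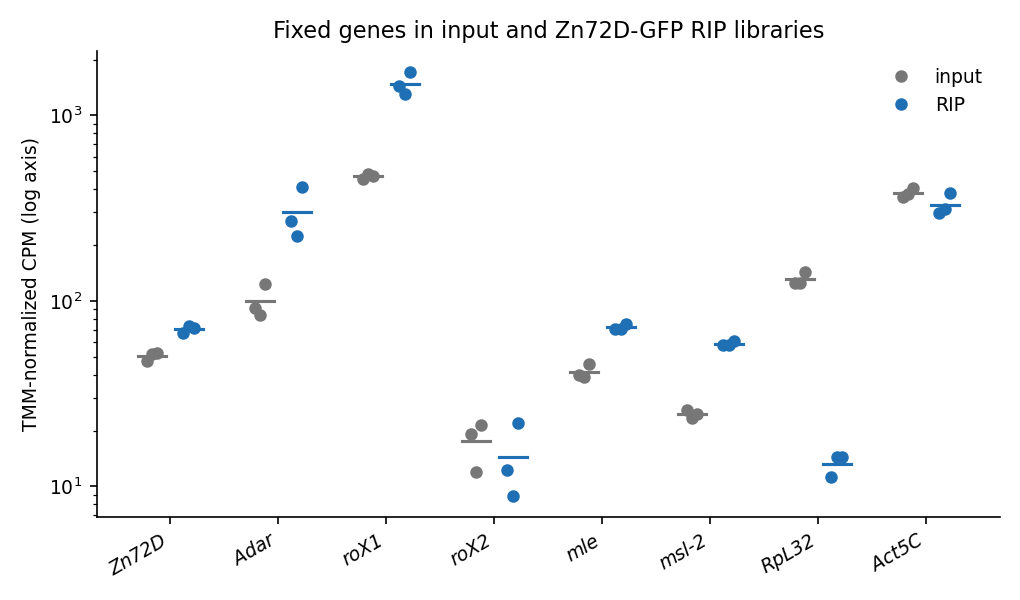
TMM-normalized CPM (log axis) of the 8 genes named in advance, with a point for each of 3 input and 3 RIP libraries and a line at the group mean. Adar, roX1, mle, msl-2 and Zn72D lie higher in RIP in every library and RpL32 lower, while the values of roX2 and Act5C overlap; under library-size scaling or in TPM the values of roX2 and Act5C turn higher, and in TPM that of RpL32 too.

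Across the transcriptome, 2362 of 11670 tested genes were enriched in RIP and 1989 depleted (edgeR quasi-likelihood test, adjusted p under 0.05). At least 2-fold changes were found in 688 enriched and 1191 depleted genes; the numbers were 335 and 299 with the length trend removed, 457 and 1458 without rRNA genes, 8888 and 106 with library size alone and 10782 and 20 in TPM. The genes with the highest fold changes under the naming rule included Vha26, a subunit of the vacuolar proton pump (4.12-fold, log2 2.04 ± 0.20, edgeR adjusted p = 0.000868), heca, the headcase gene (4.08-fold, 109 ± 3.94 to 444 ± 11.6 CPM), and beat-IIIc, a cell surface protein of the immunoglobulin superfamily (3.83-fold). The others were inaF-D, CG34106, RSG7, CG44422, lncRNA:CR46003, asRNA:CR44029 and Fs(2)Ket, the importin beta gene, at 3.75-fold to 4.10-fold. Exons of inaF-D overlap other inaF genes, those of CG34106 overlap beat-IIIa, those of asRNA:CR44029 lie opposite unc-13, and those of heca, lncRNA:CR46003 and Fs(2)Ket also lie opposite other genes, so the split of reads there is uncertain.

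The most depleted RNAs under the same rule were mostly short. The pair of identical 7SL RNA genes, between which reads cannot be told apart, fell from 14823 ± 753 to 132 ± 31.8 CPM each (log2 -6.81 ± 0.29, edgeR adjusted p = 0.000135). RNaseP:RNA, the RNA of the tRNA-processing enzyme RNase P, was 81.0-fold lower (log2 -6.34 ± 0.12, edgeR adjusted p = 2.03e-05). The nucleolar RNA snoRNA:Psi28S-291 was 48.4-fold lower, and the short protein-coding genes CG12158, CG18628, Met75Cb, CG32726 and CG11368 were 21.97-fold to 54.8-fold lower. The pseudogene CR10102 is listed at 0 counts in all 3 RIP libraries and at 1061, 1072 and 1588 in the input libraries, which gives at least 4278-fold lower against a floor of 3 counts over the RIP group. Its neighbour Arc1, a gene of retroviral Gag origin chosen after its values were seen, was 15.7-fold lower (log2 -3.97 ± 0.15, edgeR adjusted p = 0.000135); reads of CR10102 and Arc1 are uncertain where RSEM divided them. Met75Cb was 2.42 and 2.55 log2 units lower in replicate 3 than in the mean of replicates 1 and 2, in input and RIP, and the call for it ended with limma-voom (adjusted p = 0.0557), with the length trend removed (0.0746) and in TPM (0.233), within 5.75e-16 to 0.233 over the alternatives. The call for CG18628 ended in TPM (adjusted p = 0.118, within 1.08e-14 to 0.118).

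Fold changes are relative to the bulk of tested genes, whose median was 0.06 on the log2 scale. Without rRNA genes the median moved to -0.09 and the split became 1825 enriched and 2488 depleted; with library size alone it moved to 1.90 with 9386 and 173, and in log2(TPM + 1) to 2.54 with 11296 and 25. With the replicate number as a block, 3821 genes were enriched and 3230 depleted, among them all 2362 and 1989. Without both replicate 3 libraries the counts were 3015 and 3498; without RIP replicate 3 alone, 422 genes were enriched at least 2-fold. With the length trend removed, 1195 genes were enriched and 1240 depleted, of which 966 and 694 were called in the same direction before. With the block as well, 3167 were enriched and 2705 depleted, against 3821 and 3230 with the block alone.

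Genes of neuronal signalling were enriched in RIP together. Of 21 measured voltage-gated ion channel genes, 20 rose and none fell (median log2 fold change 1.08; 20 when adjusted over the list alone). They included cac, a calcium channel (log2 1.53 ± 0.10), and eag, a potassium channel (1.41 ± 0.09). The list also holds the channels SK and na and the accessory subunits Ca-beta, stj, tipE and Hk, which are not voltage-gated channels in the strict sense. Of 37 neurotransmitter receptor genes, 31 rose, 6 did not pass and none fell (median 0.94; adjusted over the list alone, 32 rose and 1 fell; with the replicate number as a block, 33 and 2), led by nAChRalpha5, an acetylcholine receptor subunit (1.81 ± 0.11), and GluClalpha, a glutamate-gated chloride channel (1.37 ± 0.10). Of 29 genes known as substrates of Adar editing, 26 rose and none fell (median 1.31; 27 rose when adjusted over the list alone); 24 of the 29 are also in other lists, 9 of them in the synaptic vesicle list.

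Synaptic and cell surface genes moved in the same direction. Of 34 genes of the synaptic vesicle cycle and active zone, 27 rose and 1 fell (median 0.83; adjusted over the list alone, 28 and 2; with the block, 30 and 2). VGlut, the vesicular glutamate transporter, rose 3.26-fold (232 ± 21.3 to 756 ± 68.2 CPM) and Rim, an active zone scaffold, 2.57-fold, while Rop, which binds syntaxin, fell 1.87-fold; the call for Rop ended in 4 of the 6 fits without a library (adjusted p up to 0.0757). Of 37 genes of cell adhesion and axon guidance, 34 rose and none fell (median 0.79; 35 adjusted over the list alone), among them the guidance cue NetB (log2 1.31 ± 0.11) and the neuroligin Nlg3 (0.94 ± 0.08). Of the 10 dosage compensation genes 6 rose and none fell (median 0.68; 6 adjusted over the list alone; 6 rose and 1 fell with the block).

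The camera test with a preset correlation called all 6 of these lists up, with adjusted p = 5.33e-16 for channels, 6.53e-16 for receptors, 4.67e-18 for editing substrates, 2.26e-10 for synaptic genes, 5.64e-16 for adhesion and 0.00104 for dosage compensation. None held with an estimated correlation, where the adjusted p was 0.189 for channels, editing substrates and adhesion, 0.215 for receptors, 0.357 for synaptic genes and 0.237 for dosage compensation. That version tests on the few residual degrees of freedom of 6 libraries, so it has little power. The preset version in turn called 9 to 16 lists in other splits of the libraries, where no gene was called. Input and RIP libraries are unequally shared between the sides of those splits, so part of the RIP-input difference stays in them. Their list calls therefore cannot tell false calls of the preset version from real ones. With the length trend removed, the adhesion list had an adjusted p = 0.145, and with the block added 0.262, its highest over 24 alternatives that began at 1.61e-20; dosage compensation then had 0.0612, within 5.14e-05 to 0.237. The medians of synaptic genes, adhesion and dosage compensation lay within the ranges of random lists matched on length and expression. Those of channels, receptors and editing substrates lay above.

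Genes for RNA-binding proteins were mostly enriched as well, though their median lay within the range of random lists matched on length and expression (0.37 to 0.75). Of 40 measured genes of RNA processing, 25 rose and 3 fell (median 0.64; adjusted over the list alone, 27 and 3, and with the block 31 and 6; camera adjusted p = 3.21e-08, and adjusted p = 0.237 with an estimated correlation). elav, a pan-neuronal splicing regulator, rose 3.36-fold (146 ± 14.1 to 492 ± 95.3 CPM) and Syp, the fly syncrip, 3.09-fold, while the splicing factor gene tra2 fell (log2 -0.79 ± 0.14; under library-size scaling and in TPM it stood at 1.04 and 2.02, below the medians of all genes). Of 27 cytoskeletal genes 15 rose and 2 fell (median 0.45; adjusted over the list alone, 16 and 2, and with the block 17 and 4; camera adjusted p = 0.00205, and adjusted p = 0.424 with an estimated correlation). sif, a Rac exchange factor, rose 2.28-fold and Map205, a microtubule-associated protein, 1.79-fold, while the myosin light chain gene sqh fell 1.77-fold. With the length trend removed the cytoskeletal list turned down (median -0.26 relative to all genes, adjusted p = 0.025, within 4.03e-08 to 0.424 over the alternatives).

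Long noncoding, antisense and CR-numbered RNAs, pseudogenes among them, numbered 433, of which 79 rose, 10 fell and 344 did not pass (median 0.45; adjusted over the list alone, 58 and 9). lncRNA:CR44024 on chromosome 4 (log2 1.74 ± 0.13) and lncRNA:CR43334 (1.54 ± 0.12), which overlaps the bantam microRNA gene and lies opposite lncRNA:CR43423, were among them. The list was called up (camera adjusted p = 0.00505) but not with an estimated correlation (adjusted p = 0.189), with the replicate block (149 up and 29 down, adjusted p = 0.0775), without input replicate 3 (adjusted p = 0.0842) or without the expression filter (adjusted p = 0.6, within 7.1e-15 to 0.6). Camera's direction for the list turned under library-size scaling and in TPM. Relative to all genes its median stayed above 0 in the first (0.38) and fell below 0 in the second (-0.66).

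Genes of the translation and respiration machinery were depleted in RIP, relative to the median gene. Of 80 cytoplasmic ribosomal protein genes, 70 fell and none rose (median log2 fold change -1.75; adjusted over the list alone, 72 fell and 1 rose, and with the block 73 and 1; camera adjusted p = 1.17e-51, and adjusted p = 0.189 with an estimated correlation). RpL29 fell 10.5-fold (log2 -3.39 ± 0.14) and RpS30 5.95-fold (-2.57 ± 0.09). Of 83 nuclear genes of oxidative phosphorylation, 63 fell and none rose (median -2.09; 64 adjusted over the list alone; 68 fell and 3 rose with the block; camera adjusted p = 1.08e-42, and adjusted p = 0.189 with an estimated correlation). ATPsynF fell 9.55-fold and ND-MNLL 9.03-fold. The ribosomal median lay within the range of random lists matched on length and expression (-2.25 to -1.65). That of oxidative phosphorylation lay below its range (-1.47 to -0.95). Under library-size scaling, where the median of all genes lies at 1.90, the list medians were 0.09 and -0.27, and in TPM 1.62 and 1.22.

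Some small structural RNAs and histone mRNAs fell. Of 67 measured small nuclear and nucleolar RNAs, 33 fell and none rose (median -2.06; 33 adjusted over the list alone; camera adjusted p = 1.18e-10, and adjusted p = 0.389 with an estimated correlation), with snoRNA:CG32479-b 46.1-fold lower. With the length trend removed this list turned up (median 0.63 relative to all genes, adjusted p = 0.00904, within 1.09e-22 to 0.389 over the alternatives), with the block 4 rose and 42 fell, and without both replicate 3 libraries 10 rose and 33 fell. Of 6 histone genes, 3 fell (median -0.45; 3 adjusted over the list alone; 3 fell and 1 rose with the block; camera adjusted p = 0.00573, and adjusted p = 0.262 with an estimated correlation), among them His4r (log2 -3.74 ± 0.10) and His3.3A (-2.34 ± 0.18). The histone call ended with the length trend removed (adjusted p = 0.182, within 4.28e-05 to 0.262).

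Secreted peptides and photoreceptor genes were lower on balance, with exceptions. Of 8 measured antimicrobial peptide genes, 6 fell and none rose (median -2.37; 6 adjusted over the list alone; camera adjusted p = 0.00016, and adjusted p = 0.189 with an estimated correlation), with Drs at 2.34 ± 0.618 CPM in input and 0.174 ± 0.0779 in RIP. Def fell 8.35-fold. Of 29 neuropeptide genes, 14 fell and 4 rose (median -1.06; 14 and 4 adjusted over the list alone; camera adjusted p = 0.000675, and adjusted p = 0.3 with an estimated correlation). Ilp2, an insulin-like peptide, fell 4.93-fold and myosuppressin, Ms, 3.50-fold, while the neuropeptide gene Proc rose 1.88-fold. Of 31 phototransduction genes, 14 fell and 6 rose (median -0.34; adjusted over the list alone, 15 and 7; camera adjusted p = 0.00609, and adjusted p = 0.585 with an estimated correlation). Arrestin 1, Arr1, fell 5.07-fold (502 ± 36.7 to 98.9 ± 10.3 CPM) and the ultraviolet rhodopsin Rh4 2.10-fold, while inaF-B, which shares exons with other inaF genes, rose 2.28-fold.

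The antimicrobial call ended with the length trend removed in the blocked fit (adjusted p = 0.0676, within 9.94e-10 to 0.189) and the neuropeptide call with the length trend removed (0.267, within 0.00021 to 0.3) and in TPM (0.174). Camera's direction for the phototransduction list turned under library-size scaling (adjusted p = 0.136) and in TPM (0.0522). Relative to all genes its median stayed below 0 in the first (-0.42) and rose above 0 in the second (0.27). With fry the adjusted p of the list was 0.0624, within 3.16e-06 to 0.585.

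Of 24 muscle genes, 10 fell and 2 rose (median -0.55; adjusted over the list alone, 10 and 3; camera adjusted p = 0.00286, and adjusted p = 0.217 with an estimated correlation). Tropomyosin 2, Tm2, fell 3.22-fold and the troponin C gene TpnC73F 2.90-fold, while sls, the fly titin, rose 1.60-fold, a call that ended without RIP replicate 2 or input replicate 1 or 2 (adjusted p up to 0.0761) and turned negative with the length trend removed. With the replicate block 15 muscle genes fell and 6 rose, without both replicate 3 libraries 16 and 5, and the list direction turned in TPM (adjusted p = 0.969, within 5.33e-08 to 0.969). Replicate 3 held less RNA of the flight muscle actin Act88F than the mean of replicates 1 and 2, by -3.33 log2 units in input and -3.46 in RIP; over the whole muscle list the medians were 0.18 and 0.03.

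The markers of other head cells were not called as lists. Of 17 glial genes, 2 fell and 1 rose (median -0.02, camera adjusted p = 0.771); the fallen were Tret1-1, a trehalose transporter (log2 -0.38 ± 0.09), and wrapper (-0.67 ± 0.19), and axo rose (0.54 ± 0.08). With the list adjusted alone 1 rose and none fell, and with the block 3 rose and 6 fell. Of 19 fat body and yolk genes 4 fell, among them Tsf1 (-0.88 ± 0.09) and Lsd-1 (-1.18 ± 0.16), and none rose (median -0.08, camera adjusted p = 0.201; 3 fell when adjusted over the list alone, 8 fell and 4 rose with the block; adjusted p = 0.0343 without both replicate 3 libraries, within 0.000177 to 0.923). Of 13 hemocyte genes, SPARC (-1.43 ± 0.18) and the collagen gene vkg (-0.38 ± 0.12) fell (median -0.09, camera adjusted p = 0.39; 1 when adjusted over the list alone, 4 fell and 1 rose with the block). The directions of these 3 medians turn in TPM relative to all genes, and with the length trend removed all 3 lists were called down (camera adjusted p = 0.00176 for glia and for fat body, 3.73e-05 for hemocytes; the highest values over the alternatives were 0.975, 0.923 and 0.696).

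Of 19 heat shock and chaperone genes 5 fell and 2 rose (median -0.25, camera adjusted p = 0.495; 5 and 2 adjusted over the list alone, 7 and 4 with the block; fry adjusted p = 0.0014, within 0.0014 to 0.737), with Hsp23 2.63-fold lower, Hsp68 1.60-fold lower and the noncoding lncRNA:Hsromega 2.30-fold higher. Of 15 clock genes 6 rose and 2 fell (median 0.30, camera adjusted p = 0.332; 6 and 3 adjusted over the list alone). Among them dco, the kinase also called doubletime, rose 1.99-fold and cwo 1.75-fold, while the cryptochrome gene cry fell 2.82-fold. The clock list was called up under library-size scaling (adjusted p = 0.00612) and in TPM (0.041). Camera's direction for it turned with the length trend removed (0.804, the highest over the alternatives), although its median stayed above that of all genes (0.13).

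With the length trend removed, the calls also ended for Nlg3 (log2 0.94 to 0.19), cwo (0.81 to 0.18), sif (1.19 to 0.30), lncRNA:Hsromega (1.201 to 0.52), sqh (-0.82 to -0.26), Hsp23 (-1.40 to -0.59) and tra2 (-0.79 to -0.47). That for wrapper ended with little change in its fold (-0.67 to -0.64); adjusted p ran from 0.0569 for wrapper to 0.371 for sqh. With the block and the length trend removed, of these only the calls for Nlg3 (adjusted p = 0.066) and cwo (0.054) ended. Without the block axo turned lower with the trend removed (log2 -0.25, adjusted p = 0.0392), and with the block too (adjusted p = 0.0135). Some calls lay near the threshold: those for wrapper and vkg each ended in 5 of the 6 fits without a library (log2 -0.51 to -0.74 for wrapper and -0.28 to -0.46 for vkg in those fits), and that for Tret1-1 without input replicate 2 (log2 -0.34, adjusted p = 0.0987, within 6.09e-06 to 0.0987). With the block all 3 were called (adjusted p = 0.00142 for wrapper, 0.00032 for vkg and 0.000534 for Tret1-1). Exons of elav, VGlut, tra2, axo, sls, Lsd-1, RpL29, ATPsynF, His3.3A, Hsp68 and cry lie opposite exons of other genes, and those of msl-2, lncRNA:Hsromega and ND-MNLL overlap another gene on the same strand, so those counts are uncertain.

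**Figure D3:**
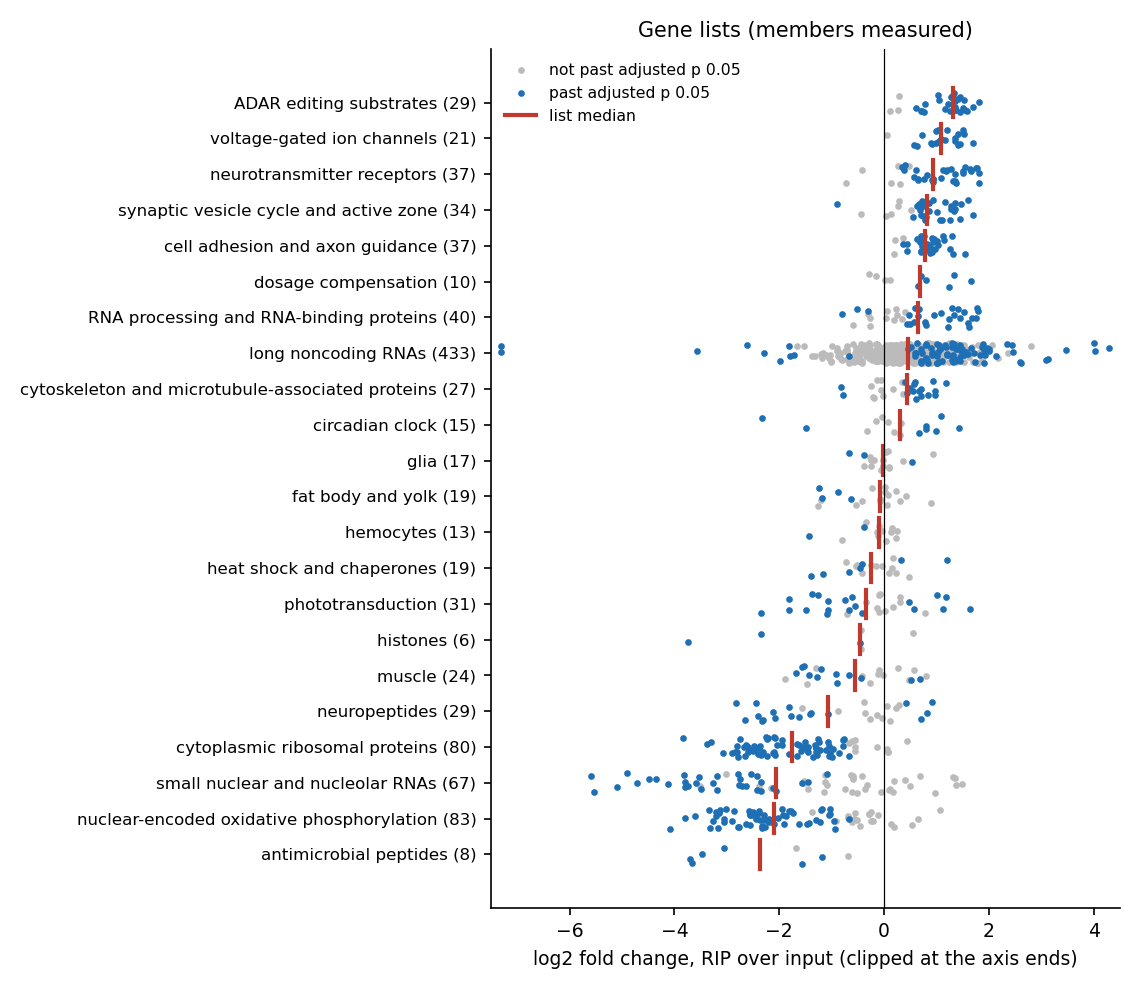
Log2 fold change (RIP over input) of every measured member of the 22 gene lists, with members past an adjusted p of 0.05 in blue, the others in grey and the list median as a red line; the number of members is in brackets. Medians run from -2.37 for antimicrobial peptides to 1.31 for Adar editing substrates, as scaled by TMM; with library size alone the median of all genes lies at 1.90.

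The fold change rose with transcript length across genes. Genes under 500 bases were enriched in 1.75% and depleted in 53.6% of 401 cases (median log2 fold change -1.62), genes of 2000 to 4000 bases in 27.4% and 4.69% of 3559 (median 0.30), and genes of 8000 bases or more in 78.4% and 0% of 245 (median 0.75). The Spearman correlation across the 11670 genes was 0.64 for transcript length, and 0.67, 0.65 and 0.58 in the 3 pairs of libraries with the same number. It was 0.55 for coding length, 0.49 for 3′ UTR length, 0.35 for intron length and -0.07 for the mean input TPM. Genes are not independent replicates, so no p is given for these 5 relations.

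**Figure D4:**
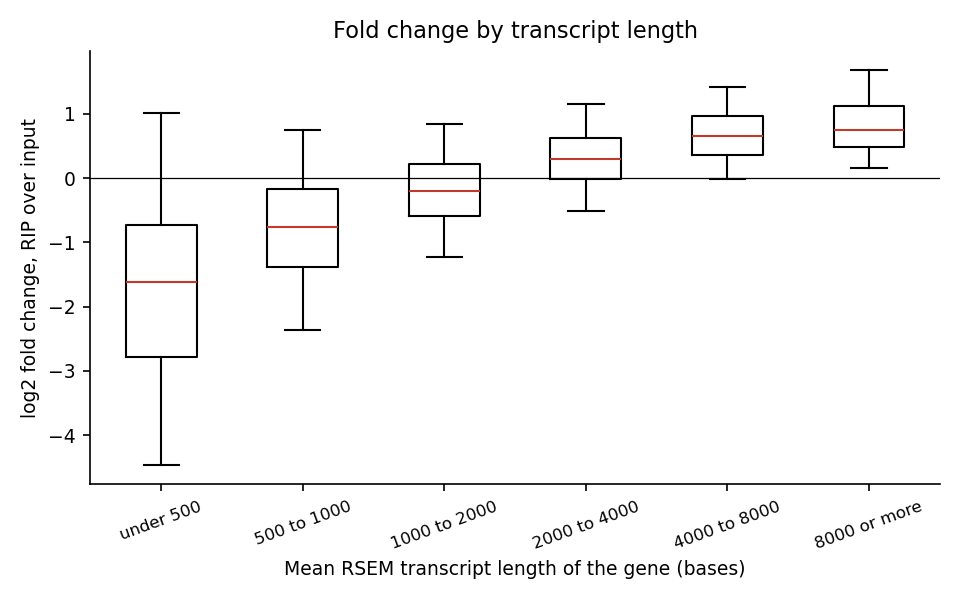
Log2 fold change (RIP over input) of tested genes by mean RSEM transcript length (bases); boxes span the quartiles with the median in red, and whiskers the 5th to 95th percentiles. The median runs from -1.62 under 500 bases to 0.75 at 8000 bases or more.

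Because Zn72D acts in dosage compensation, X-linked genes were compared with autosomal genes. On the X chromosome 499 of 1900 tested genes (26.3%) were enriched, against 1853 of 9739 autosomal genes (19.0%), an odds ratio of 1.52 (95% interval 1.35 to 1.70, two-sided Fisher's exact test, p = 2.89e-12 over genes, which are not independent). X-linked genes as a set were not called (median log2 fold change 0.19; camera adjusted p = 0.254, and adjusted p = 0.816 with an estimated correlation). Their median length was 1993 bases, against 1760 to 1796 on the arms of chromosomes 2 and 3. The X-linked median lay above the middle 95% of medians of random lists matched on length and expression (0.07 to 0.14). Those lists were drawn gene by gene, while X-linked genes had an estimated correlation of 0.0896, so the range may be too narrow. The odds ratio in TPM was 1.30 (Fisher's exact test, p = 0.101), within 1.41e-15 to 0.101 over 22 alternatives, and with the block 752 X-linked genes were enriched.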

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

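The settings without rRNA genes alone, with thinned libraries or without both replicate 3 libraries were chosen after seeing the data, as were the gene families. Over all settings, named genes kept direction and side of the threshold in 1628 comparisons, turned direction in 53, lost the call in 47 and gained it in 6; 18 of the turns came with library size only and 27 in TPM, where all genes shift upward together. For gene lists the numbers were 467, 20, 30 and 10, and for the 4 counts of genes 67 stayed within 1.5 times, 14 fell below and 7 rose above. For lists, the direction is that of camera and the value printed is the list's median log2 fold change minus that of all genes, so the signs can differ. In simulated data at the depth and spread of these libraries 43.3% of 2-fold changes were recovered, with few genes changed and no rRNA shift. Depth was not varied there. Thinning all libraries to 5864713 non-rRNA counts left 582 genes enriched and 1136 depleted at least 2-fold, against 688 and 1191. With 10 splits of the 6 libraries, a share under 0.05 cannot be reached. The real split was 1 of 10 with as many genes (4351, highest other 0), 1 of 10 with as many genes changed at least 2-fold (1879, highest other 0) and 1 of 10 with as many lists (17, highest other 16). Among the splits that part all 3 same-numbered pairs, the others called 0 genes and 16, 13 and 12 lists; the remaining splits part fewer pairs and called 9 to 14 lists. In every other split the sides hold unequal numbers of input and RIP libraries, so part of the RIP-input difference stays in it. The list counts of those splits therefore do not measure false calls. How much of them this difference explains was not tested. None of the 17 lists held with an estimated correlation.

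With library size only, the counts were 9386 enriched, 173 depleted, 8888 enriched at least 2-fold and 106 depleted at least 2-fold. The log2 fold changes turned to 1.54 for roX2, 1.62 for Act5C, 1.04 for tra2, 0.94 for Rop, 0.77 for Rh4, 1.47 for Tret1-1, 1.17 for wrapper, 0.15 for Tm2, 0.31 for TpnC73F, 0.96 for Tsf1, 0.68 for Lsd-1, 0.40 for SPARC, 1.45 for vkg, 0.43 for Hsp23, 1.16 for Hsp68, 0.34 for cry, 0.0115 for Ms and 1.02 for sqh. Lists that turned, or lost or gained a call, were phototransduction (-0.42), glia (-0.0832), muscle (-0.61), hemocytes (-0.14), long noncoding RNAs (0.38), heat shock (-0.30) and clock (0.24), with the V-ATPase family at -0.13. This scaling keeps the rRNA share in the library size, which moves the median of all genes to 1.90.

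In log2(TPM + 1), where that median is 2.54, the counts were 11296, 25, 10782 and 20. TPM keeps rRNA in its sum too, but it also divides by effective length, so the rRNA share alone need not give this median. The values turned to 2.76 for roX2, 0.19 for RpL32, 3.12 for Act5C, 2.02 for tra2, 2.35 for Rop, 1.04 for Arr1, 2.32 for Rh4, 2.92 for Tret1-1, 1.92 for wrapper, 1.69 for Tm2, 1.65 for TpnC73F, 2.46 for Tsf1, 2.06 for Lsd-1, 1.82 for SPARC, 2.83 for vkg, 0.30 for Def, 0.94 for RpS30, 0.24 for RpL29, 0.23 for ATPsynF, 0.17 for ND-MNLL, 1.15 for His3.3A, 1.60 for Hsp23, 2.10 for Hsp68, 1.81 for cry, 1.52 for Ms, 1.01 for Ilp2 and 2.498 for sqh. Lists were phototransduction (0.27), glia (0.53), muscle (0.11), fat body and yolk (0.52), hemocytes (0.0728), long noncoding RNAs (-0.66), heat shock (-0.0514), clock (0.94) and neuropeptides (-1.02), with V-ATPase at 0.43 and mitochondrial ribosomal proteins at -0.82, whose call ended. The X-linked odds ratio was 1.30, and the rhos were 0.567 for transcript, 0.452 for coding, 0.57 for 3′ UTR and 0.453 for intron length.

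With the length trend removed, the counts were 1195, 1240, 335 and 299, and with the block added 3167, 2705, 719 and 466. The values turned, without and with the block, to -0.0056 and -0.00553 for Zn72D, 0.79 and 0.67 for roX2, -0.25 and -0.25 for axo and -0.31 and -0.31 for sls. Lists were, in the same order, adhesion (0.0218 and 0.0209), glia (-0.34 and -0.35), fat body and yolk (-0.40 and -0.43), hemocytes (-0.73 and -0.73), small nuclear and nucleolar RNAs (0.63 and 0.78), clock (0.13 and 0.13), neuropeptides (-0.0434 and -0.0656), cytoskeleton (-0.26 and -0.27) and V-ATPase (0.25 and 0.24). Histones (0.14) changed without the block, and dosage compensation (0.12) and antimicrobial peptides (-1.20) with it. These follow from the removal of a trend that RIP itself may share, as weighed among the other observations.

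With the replicate number as a block 3821 genes were enriched and 3230 depleted, the long noncoding list (0.40) lost its call and V-ATPase stood at -0.13. The block also brought the calls of roX2 and Act5C and changed no other call of a named gene or fixed list. With an estimated correlation, calls ended for dosage compensation (0.62), editing substrates (1.26), RNA-binding proteins (0.59), synaptic genes (0.77), channels (1.02), receptors (0.89), adhesion (0.73), phototransduction (-0.40), muscle (-0.61), antimicrobial peptides (-2.43), ribosomal proteins (-1.80), oxidative phosphorylation (-2.15), small nuclear and nucleolar RNAs (-2.12), long noncoding RNAs (0.40), histones (-0.51), neuropeptides (-1.12) and cytoskeleton (0.39). In that version camera tests on the few residual degrees of freedom of 6 libraries, so it has little power here. Ribosomal proteins and long noncoding RNAs, with camera adjusted p = 1.17e-51 and 0.00505 at the preset correlation, both stood at 0.189. These lost calls therefore do not tell the lists apart. The estimated correlation of the long noncoding list (0.00653) was below the preset 0.01, so a higher correlation is not what ended that call. fry asks whether a list's genes move one way on balance, not whether they differ from other genes. By that other question phototransduction (-0.40) lost and heat shock (-0.31) gained a call; the values in brackets are relative to all genes and are not what fry tests.

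At an adjusted p of 0.01, 1442 genes were enriched and 1105 depleted. Without both replicate 3 libraries 3498 were depleted, fat body and yolk (-0.18), roX2 (-0.71) and Act5C (-0.44) gained a call, V-ATPase stood at -0.27, and rho was 0.458 for 3′ UTR and 0.32 for intron length. Genes enriched at least 2-fold numbered 454 without rRNA and short genes and 457 without rRNA genes. Without a filter the long noncoding list (0.47) lost its call and the rhos were 0.361, 0.445, 0.388 and 0.167 for transcript, coding, 3′ UTR and intron length; in thinned libraries rho was 0.507 for 3′ UTR length. The cause was not tested. Leaving out each library gave 422 (without RIP replicate 3) to 917 (without input replicate 3) genes enriched at least 2-fold, -0.23 to 0.0483 for glia, 0.38 (without input replicate 3, where the call ended) to 0.52 for long noncoding RNAs, and -0.24 to -0.089 for the gene family V-ATPase subunits. The direction for glia turned without RIP replicate 1 and without input replicate 3, and for V-ATPase without RIP replicate 3.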

Other observations

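The gene families here and the tests of fragment length, thinning and depth were chosen after the results were seen. So were the Y-linked, testis, accessory gland and flight muscle lists. Chromosome 4 was not in the plan either, which compared X-linked with autosomal genes only. The beat, side, dpr and DIP genes, immunoglobulin superfamily cell surface proteins of neurons, were higher in RIP: of 53 measured, 42 rose and none fell (median log2 fold change 0.82, camera adjusted p = 5.73e-14, and adjusted p = 0.167 with an estimated correlation); 2 of them are in the fixed lists. Of 47 proteasome subunit genes, 29 fell and none rose (median -1.02, camera adjusted p = 3.4e-08, and adjusted p = 0.166 with an estimated correlation). With the replicate block 33 fell and 4 rose. Those not passing in the main fit, apart from Prosalpha4, Rpn2 and Rpn6, have a T or R added to the name of a subunit. Most of these variants were lower in replicate 3, as Rpn12R at 3.28, 1.75 and 0.566 CPM in input 1 to 3. Of 73 mitochondrial ribosomal protein genes, 64 fell and none rose (median -1.36, camera adjusted p = 3.48e-18, and adjusted p = 0.161 with an estimated correlation; 69 fell and 2 rose with the block; the call ended in TPM, adjusted p = 0.155, within 1.04e-21 to 0.155 over the alternatives). Of 23 odorant-binding protein genes, which encode small secreted proteins, 13 fell and none rose (median -1.98, camera adjusted p = 4.38e-08, and adjusted p = 0.166 with an estimated correlation; 17 fell and 2 rose with the block).

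Genes of the vacuolar proton pump went both ways. Of 26 V-ATPase genes, 6 rose and 8 fell (median -0.07, camera adjusted p = 0.691). Those not passing included Vha100-3, Vha68-3 and Vha36-2, which were lower in replicate 3 in both groups. Vha26 (log2 2.04 ± 0.20), Vha16-1 (1.81 ± 0.22, from 761 ± 110 to 2673 ± 699 CPM) and VhaAC45 (1.54) rose, while Vha13 (-1.93) and VhaM9.7-a (-1.37) fell. Set against random lists of the same length and expression (the range of the middle 95% of their medians), the medians of editing substrates (1.31, against 0.61 to 1.05), receptors (0.94, against 0.39 to 0.70), channels (1.08, against 0.52 to 1.03), long noncoding RNAs (0.45, against -0.35 to -0.18) and the beat, side, dpr and DIP genes (against 0.23 to 0.52) lay above. Those of oxidative phosphorylation (-2.09, against -1.47 to -0.95), the proteasome (against -0.55 to -0.10), mitochondrial ribosomal proteins (against -0.93 to -0.51), odorant-binding proteins (against -1.60 to -0.57), phototransduction (-0.34, against -0.11 to 0.48) and neuropeptides (-1.06, against -0.90 to -0.15) lay below. So did those of glia (-0.02, against 0.06 to 0.62), hemocytes (-0.09, against 0.11 to 0.72), antimicrobial peptides (-2.37, against -1.70 to -0.25) and cytoskeleton (0.449, against 0.459 to 0.909), the last although its median is above 0, and muscle lay at the lower end (-0.5518, against -0.5514 to 0.37). Those of cytoplasmic ribosomal proteins (-1.75, against -2.25 to -1.65), synaptic genes (0.83, against 0.57 to 0.98), adhesion (0.79, against 0.51 to 0.85), RNA-binding proteins (0.64, against 0.37 to 0.75) and dosage compensation (0.68, against 0.15 to 0.84) lay within the range, as did those of fat body and yolk (-0.08, against -0.22 to 0.43), small nuclear and nucleolar RNAs (-2.06, against -2.16 to -1.37), histones (-0.45, against -1.61 to 0.06), heat shock (-0.25, against -0.27 to 0.43), clock (0.30, against 0.11 to 0.78) and V-ATPase (against -0.36 to 0.31).

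Longer transcripts were higher in RIP (rho 0.64). Fragment length accounted for little: the lengths RSEM used predict a median of -0.15 for 626 genes of 200 to 600 bases, against -1.45 observed, a ratio of 0.102. Thinning all libraries to the same non-rRNA count left rho at 0.657, which argues against deeper non-rRNA sequencing of RIP; total depth and the rRNA share were not matched. A relation carried by the 3′ UTR rather than the coding part was not seen, since the partial rhos differed by -0.10, -0.09 and 0.05 in the 3 pairs (the smallest -0.101). Binding of Zn72D to long RNAs, background RNA held by the beads and loss of short RNA in the precipitate remain open as hypotheses, as no mock precipitation was analysed here.

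Replicate 3 stood apart from replicates 1 and 2 in both groups. More testis material in replicates 1 and 2 is a candidate explanation, although the samples are given as heads: the 5 Y-linked fertility genes were -2.56 in input and -2.03 in RIP (median log2 difference), testis genes -2.48 and -2.25, and male accessory gland genes -2.38 and -2.24, against 0.17 and -0.01 over all genes. The flight muscle genes Act88F (-3.33 and -3.46), fln (-3.34 and -3.50) and TpnC4 (-2.83 and -2.84) were lower too, and Strn-Mlck by less (-0.44 and -0.68). The genes wupA, up, Mf and Mhc (0.18 and 0.01 for Mhc) were not, and the median of these 8 genes was -0.13 and -0.33. Depth would move the groups apart, as replicate 3 is the deepest input and the shallowest RIP, and the deviations correlated at 0.848. roX1 and roX2 belong to the dosage compensation complex, whose msl-2 is translated in males only. They were not lower in replicate 3. In replicates 1 to 3, roX1 had 453, 482 and 471 CPM in input and 1434, 1307 and 1715 in RIP. For roX2 the values were 19.3, 12.0 and 21.4 in input and 12.2, 8.93 and 21.95 in RIP. These values argue against a share of males lower by as much as the testis genes. A smaller difference in that share and a difference in body parts stay open.

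Genes of chromosome 4 were higher in RIP: 66 of 96 rose and 5 fell (median 0.94, camera adjusted p = 4.45e-14, and adjusted p = 0.816 with an estimated correlation), among them pan (log2 1.77), mGluR (1.503), unc-13 (1.45) and onecut (1.34), chosen after their values were seen. The middle 95% of medians of lists matched on transcript length and expression reached up to 0.551, below the chromosome 4 median. Matched lists were drawn gene by gene, while chromosome 4 genes had an estimated correlation of 0.402, so such ranges may be too narrow. Lists matched on 3′ UTR and intron length reached 0.54, against 0.91 for the 79 genes with both. Binding of Zn72D to RNAs of this chromosome, and sequence content, which was not tested, remain open.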
